A study of Homo sapiens with 18 samples.

How the data were processed

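Total RNA of the human breast carcinoma lines MDA-MB-361, MDA-MB-453 and MCF7 was measured in 18 libraries, 3 control and 3 abemaciclib libraries of each line. Abemaciclib was given for 7 days at 500 nM to MDA-MB-361 and MDA-MB-453 and at 250 nM to MCF7. What the controls received is not given in the sources used here, nor is whether the replicates came from separate cultures or days. Libraries were made with a targeted kit (Ion AmpliSeq Transcriptome Human Gene Expression), which amplifies 1 product of about 110 bp for each RefSeq gene, so values say nothing about isoforms. The deposited values are whole-number read counts for each targeted gene, made by the authors on the hg19 build, with no normalization. The aligner, the counting program and the strand are not given in the sources used here.

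The table held 20812 entries, and all 18 of its columns matched a sample. Of the entries, 10 were ERCC spike-in controls with 2 counts in 1 library, and they were left out. Another 28 carried names that a spreadsheet had turned into dates, 2 of these names being duplicated. They stayed in the tests and are never named. Library totals over the 20802 genes ran from 7913151 counts (MDA-MB-453 abemaciclib replicate 2) to 14654854 (MDA-MB-453 control replicate 1). Within groups, counts of replicates differed by more than counting error (chi-square over degrees of freedom 6.42 to 82.0 in 18 pairs), and no pair was identical.

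Counts were analysed in edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr (minimum count 10, minimum total 15, 6 groups), which left 13007 genes and set 7795 aside. Library sizes were scaled by TMM. A negative binomial quasi-likelihood model with a mean for each of the 6 groups was fitted to all 18 libraries, with 12 residual and 6.67 prior degrees of freedom and a common biological coefficient of variation of 17.9%. glmQLFTest gave two-sided tests of treated against control in each line, of their average over the lines and of the 3 differences between lines. A test of any difference among the lines (F-test with both contrasts) served for genes in the comparison of responses. P-values were adjusted by Benjamini and Hochberg over all genes tested, with 0.05 as the threshold. Fold changes used a prior count of 0.125. CPM in levels were computed with TMM-adjusted library sizes, and log2 CPM for principal components and correlations with a prior count of 2.

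Where a group of 3 libraries had 0 counts, a fold is given as a lower bound against a floor of 3 counts over the group, scaled by raw totals. Where it had 1 to 3, the ratio of CPM is given with an exact 95% counting interval. No fold is given where both groups were at or under the floor. Bounds and intervals cover counting error only.

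Before the data were examined, 31 lists of genes were fixed, and with them the contrasts, the main tests, most alternatives and the rule for naming genes. The lists were DNA replication and E2F target genes, G2/M and mitosis genes, CDK, cyclin, RB and CDK inhibitor genes, DNA methylation machinery, antigen processing and MHC class I genes, interferon-stimulated genes, double-stranded RNA and nucleic acid sensing genes, interferon ligands and receptors, immune checkpoint and costimulatory ligands, senescence-associated secretory genes, p53 target genes, cholesterol biosynthesis genes, lysosome genes, oxidative phosphorylation genes, ribosomal protein genes, MYC target and ribosome biogenesis genes, estrogen receptor target genes, luminal epithelial genes, basal, myoepithelial and squamous epithelial genes, mesenchymal genes, ERBB family and MAPK feedback genes, unfolded protein response genes, heat shock genes, immediate early genes, apoptosis regulators and replication-dependent histone genes, 3 lists of genes typical of other cell types (fibroblast genes, endothelial genes and leukocyte genes), MHC class II genes and cancer-testis antigen genes. Of their genes, 9 were not in the table. Lists with at least 5 genes tested entered limma's camera test (limma 3.58.1, inter-gene correlation preset at 0.01), 28 in all, with p-values adjusted over these lists. The leukocyte, MHC class II and cancer-testis lists had too few. Several lists share genes, such as interferon-stimulated genes with nucleic acid sensing (5) and with antigen processing genes (3), and mesenchymal with fibroblast genes (2). Camera's preset correlation understates the dependence of genes regulated together, so the test was repeated with an estimated correlation.

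Genes were named by rule. For each line these were the 6 highest and 6 lowest log2 fold changes among genes with an adjusted p under 0.05, a mean CPM of at least 10 over the 6 libraries of the line and all 3 treated libraries on one side of all 3 controls. For each list described, up to 4 members with the smallest adjusted p in the line, or in the average, were added. CDK4, CDK6, CCND1, CCNE1, CCNE2, RB1, E2F1, CDKN1A, MKI67, DNMT1, UHRF1, B2M, HLA-A, HLA-B, TAP1, NLRC5, STAT1, CD274, ERBB2 and ESR1 were always eligible. For each difference between lines, the 4 largest in each direction were taken. They had an adjusted p of the difference under 0.05 and a mean CPM of at least 10 over 12 libraries. For genes changed the same way in all 3 lines, 6 in each direction were those whose smallest absolute log2 fold change was largest, with a mean CPM of at least 10 in each line. All tested members of the DNA methylation machinery and of the interferon ligands and receptors could be named. Identity markers were ERBB2, ESR1, PGR, AR, GATA3, KRT8, KRT18 and VIM. The text names only some of the genes that the rule allows. The interferon lambda genes, IFNB1 and the genes of the lists not tested were added after their values were seen.

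Pairing by number was checked by correlating, across genes, each library's deviation from its group mean between the treatments. Same-numbered libraries correlated at 0.24 to 0.53 in MDA-MB-361 and 0.13 to 0.52 in MDA-MB-453. There 6 of 6 and 5 of 6 libraries matched their own number best. In MCF7 they correlated at 0.00 to 0.03, with 3 of 6. Replicate number as a block was therefore tried as an alternative for all lines and, after this check, for MDA-MB-361 and MDA-MB-453 only.

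As a test, counts were simulated with the depths and dispersions of the 18 libraries. In each line 50 genes with a control CPM of at least 10 were changed at each of 4 folds. At 1.5-fold, 12, 13 and 12 of 50 were recovered in MDA-MB-361, MDA-MB-453 and MCF7. At 2-fold the numbers were 38, 40 and 41, and at 4-fold and 8-fold 50 of 50 in every line. False calls were 9 of 159, 12 of 165 and 7 of 160. With so few changed genes, these rates need not hold in the data.

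Alternatives were RLE factors, library size alone, no low-count filter, a mean CPM of at least 10, the replicate block, each library left out in turn, DESeq2 1.42.0, each line fitted alone, camera with an estimated correlation, and fry for the lists. A limma alternative planned for values that are not counts was not run, since the values are counts. Other splits of the libraries were counted, all 10 within each line and 59 random relabellings of treatment within lines for results over several lines. GC content and transcript length came from GENCODE 29 on GRCh38, a build other than the hg19 of the counts, by gene name (11915 of 13007 genes, 91.6%). No positions are given for that reason. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.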

Results

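RNA was counted gene by gene in 18 libraries from 3 established human breast cancer lines, MDA-MB-361, MDA-MB-453 and MCF7. Each line had 3 control libraries and 3 libraries from cells kept for 7 days in abemaciclib, an inhibitor of the kinases CDK4 and CDK6. The dose was 500 nM in MDA-MB-361 and MDA-MB-453 and 250 nM in MCF7, so dose and line cannot be separated where MCF7 is compared with the others. Library totals ran from 10742780 to 14284670 counts in MDA-MB-361 controls and 10591969 to 13535939 in its treated libraries. They ran from 10176927 to 14654854 and 7913151 to 11810159 in MDA-MB-453, and from 8596220 to 10483107 and 9059035 to 12625210 in MCF7. Levels are counts-per-million values (CPM), mean ± SD of 3 libraries, control first. Changes are log2 fold changes ± SE of treated over control from edgeR's quasi-likelihood test, two-sided, with Benjamini-Hochberg adjusted p-values over 13007 genes. A gene is said to have risen or fallen only where its adjusted p was under 0.05, and a list of genes to have shifted where the adjusted p of limma's camera test over 28 lists was under 0.05. A list's median is that of its genes' log2 fold changes. A bounded median is given beside it where it differs. In it a gene with a group at 0 counts takes the bound that 3 counts allow, and a gene with both groups at 3 counts or fewer is left out. Counts of genes that rose or fell are over all genes tested, and counts adjusted over the list alone follow where they differ. A range after an alternative's adjusted p covers all alternatives to that result but fry, which sets a list against no change rather than other genes and passed more lists. The labels do not say whether replicates came from separate cultures, so these p-values measure only the spread between these libraries. Reads of PCR products without molecular identifiers are not independent molecules, so intervals and floors cover counting error only. Values of closely related genes (HLA, histone and HSPA1 genes, and interferon lambda genes) are uncertain because such genes can share reads.

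Marker levels separated the lines. In controls, the receptor tyrosine kinase gene ERBB2 stood at 230.4 ± 77.0 CPM in MDA-MB-361, 108 ± 67.7 in MDA-MB-453 and 22.0 ± 2.17 in MCF7. The estrogen receptor gene ESR1 was counted at 181 ± 10.7 CPM in MDA-MB-361 and 202 ± 2.21 in MCF7 but had no counts in MDA-MB-453. The progesterone receptor gene PGR stood at 52.2 ± 8.06, 1.83 ± 0.420 and 0.401 ± 0.179 CPM in those lines. MDA-MB-453 had the most androgen receptor RNA (AR 169 ± 26.0, against 56.2 ± 5.24 in MDA-MB-361 and 33.1 ± 3.43 in MCF7). The luminal transcription factor gene GATA3 was lowest in MDA-MB-361 (111 ± 45.3 CPM) and highest in MCF7 (720.3 ± 53.1). The luminal keratin gene KRT8 stood at 592 ± 135, 342 ± 146 and 1566 ± 105 CPM and KRT18 at 962 ± 122, 580.02 ± 118 and 1712 ± 164 in MDA-MB-361, MDA-MB-453 and MCF7. The mesenchymal gene VIM was at 0.499 ± 0.248 CPM in MDA-MB-361, 0.546 ± 0.686 in MCF7 and without counts in MDA-MB-453.

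The first principal component of the 6 libraries parted treated from control in every line and held 68.1% of the variance in MDA-MB-361, 69.3% in MDA-MB-453 and 87.0% in MCF7. The second component held 16.8%, 17.8% and 3.58%, and in MDA-MB-361 and MDA-MB-453 it set the replicate 1 libraries of both treatments apart from replicates 2 and 3. Deviations from the group means correlated at 0.44 to 0.54 across genes among the 4 replicate 1 libraries of these lines (6 pairs).

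**Figure D1:**
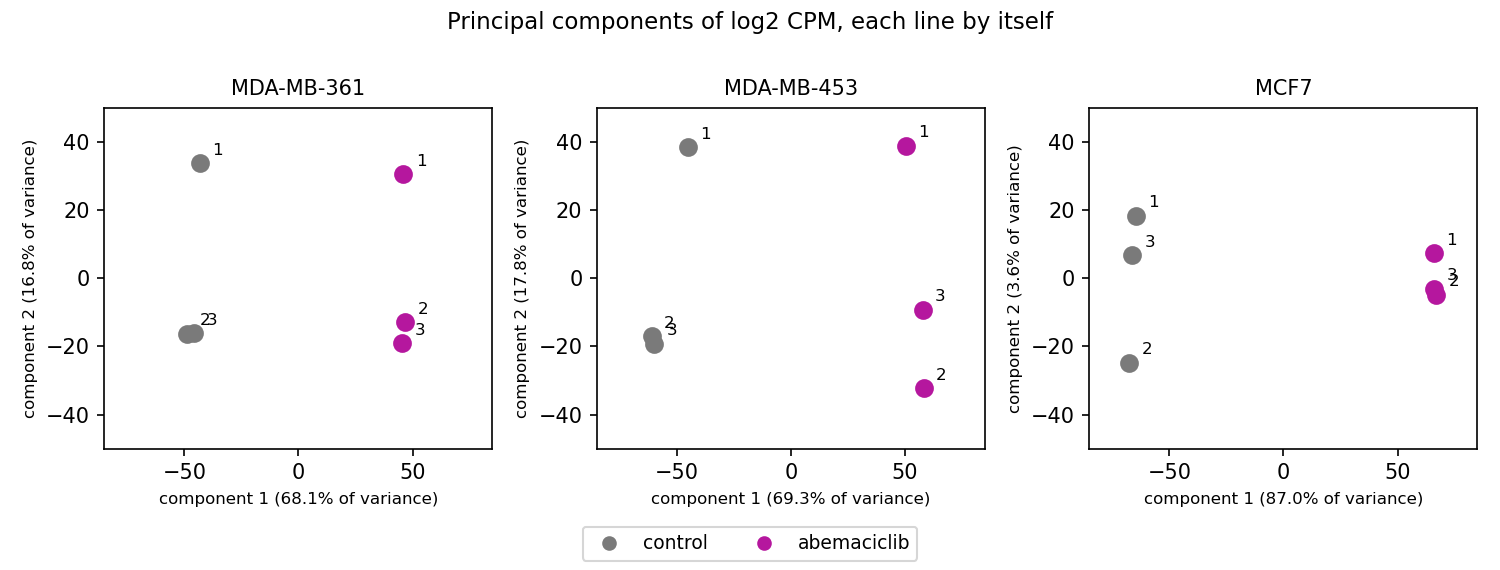
Principal components of log2 CPM in each line, with component 1 on the horizontal and component 2 on the vertical axis, 1 point per library and its replicate number beside it. Component 1 (68.1%, 69.3% and 87.0% of the variance in MDA-MB-361, MDA-MB-453 and MCF7) parts treated from control, and component 2 sets replicate 1 apart in MDA-MB-361 and MDA-MB-453.

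The comparison within MDA-MB-361 asks which RNAs changed over a week of CDK4 and CDK6 inhibition. Genes of DNA replication, mitosis and histone supply fell almost without exception, cholesterol synthesis genes fell and lysosome genes rose. Interferon-stimulated genes rose in part only. Of 13007 genes, 3867 changed (1860 rose and 2007 fell), 730 rising and 938 falling at least 2-fold, and 5917 passed with replicate number as a block in MDA-MB-361 and MDA-MB-453. The vitamin B12 binding protein gene TCN1 rose from 500.01 ± 72.3 to 6612 ± 645 CPM (log2 fold change 3.73 ± 0.31, adjusted p = 2.82e-08). Other large rises were those of VSTM2A (4.87 ± 0.39), TTR (4.54 ± 0.31), BHLHE40 (3.47 ± 0.23) and UGT2B15 (3.04 ± 0.28), with adjusted p at most 2.33e-07. The largest falls included KIFC1 (-5.72 ± 0.55), RRM2 (-5.25 ± 0.24) and SPC25 (-5.08 ± 0.49), coding for a spindle kinesin, a ribonucleotide reductase subunit and a kinetochore protein, with adjusted p at most 2.48e-07.

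Of 56 DNA replication and E2F target genes, 55 fell and 1 did not pass (median -1.93, adjusted p = 9.17e-73). CDC45 of the replicative helicase went from 64.7 ± 0.667 to 9.31 ± 0.830 CPM. Of 66 G2/M and mitosis genes, 65 fell and 1 did not pass (66 fell adjusted over the list alone, median -3.45, adjusted p = 1.69e-92). The proliferation marker MKI67 went from 96.1 ± 14.3 to 2.68 ± 1.72 CPM (log2 fold change -5.20 ± 0.38, adjusted p = 5.52e-09) and the mitotic kinase gene PLK1 from 186 ± 38.0 to 5.57 ± 2.38 CPM. Of 35 replication-dependent histone genes, 1 rose, 33 fell and 1 did not pass (median -2.57, adjusted p = 9.12e-68). HIST1H3F went from 451 ± 9.15 to 11.9 ± 2.90 CPM. Of 22 CDK, cyclin, RB and CDK inhibitor genes, 4 rose, 10 fell and 8 did not pass (5 rose and 12 fell adjusted over the list alone, median -0.38, adjusted p = 0.000242). Within this list CCNE2 (-4.47 ± 0.23, adjusted p = 5.16e-11), E2F1 (-1.62 ± 0.16, adjusted p = 2.88e-07) and CCNE1 (-1.11 ± 0.20, adjusted p = 0.000267) fell. The cyclin D1 gene CCND1 (1.30 ± 0.16, adjusted p = 4.35e-06) and CDK6 (1.05 ± 0.16, adjusted p = 4.84e-05) rose. CDK4 (-0.27 ± 0.14, adjusted p = 0.165), RB1 (-0.34 ± 0.14, adjusted p = 0.0798) and the CDK inhibitor gene CDKN1A (-0.43 ± 0.18, adjusted p = 0.0752) did not pass. With the replicate block RB1 and CDKN1A did (adjusted p = 0.0195 and 0.0114, ranges 0.0116 to 0.283 and 0.00977 to 0.218). In the DNA methylation machinery (17 genes), 6 fell and 11 did not pass (median -0.33, adjusted p = 5.22e-06). The maintenance methyltransferase gene DNMT1 (-1.29 ± 0.18, adjusted p = 1.65e-05) and UHRF1 (-2.80 ± 0.15, adjusted p = 8.99e-11), whose product brings DNMT1 to replicated DNA, both fell.

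Of 58 interferon-stimulated genes, 21 rose, 4 fell and 33 did not pass (22 rose and 6 fell adjusted over the list alone, median 0.69, adjusted p = 0.00187, but adjusted p = 0.654 with an estimated correlation, range 1.78e-06 to 0.654, and 0.0567 with fry). STAT1, a transcription factor of interferon signalling, rose from 173 ± 6.52 to 288 ± 9.47 CPM (log2 fold change 0.74 ± 0.21, adjusted p = 0.0106). SP100 (2.58 ± 0.39) and GBP3 (2.13 ± 0.34) rose too, while USP18, a negative regulator of the pathway, fell (-0.84 ± 0.13, adjusted p = 8.75e-05). Of 17 double-stranded RNA and nucleic acid sensing genes, 7 rose and 2 fell (7 rose and 3 fell adjusted over the list alone, median 0.02, adjusted p = 0.368). Among these OAS1 rose (2.41 ± 0.49, adjusted p = 0.000955) and IRF7 fell (-1.03 ± 0.25, adjusted p = 0.00364). Of 21 antigen processing and MHC class I genes, 5 rose (median 0.36, adjusted p = 0.0935). B2M (0.56 ± 0.25, adjusted p = 0.102), HLA-A (0.59 ± 0.24, adjusted p = 0.0784), the peptide transporter gene TAP1 (0.36 ± 0.21, adjusted p = 0.211) and NLRC5, the transactivator of MHC class I genes (-0.47 ± 0.43, adjusted p = 0.453), did not pass. B2M and HLA-A did with the replicate block (adjusted p = 0.0103 and 0.0228, ranges 0.000674 to 0.246 and 0.000287 to 0.262). HLA-B had 3 counts in controls and 7 in treated libraries, a ratio of 2.33-fold (95% counting interval 0.531 to 13.9). CD274, the PD-L1 gene, was too low to be tested and had 5 counts over the 3 control and 9 over the 3 treated libraries. Of 7 interferon ligands and receptors, 2 rose (median 0.34, adjusted p = 0.368). Of 13 immune checkpoint and costimulatory ligands, 5 rose (median 0.69, adjusted p = 0.154). CD47, coding for the signal that blocks phagocytosis, rose (1.02 ± 0.18, adjusted p = 0.000289). None of these 4 lists of sensing, antigen presentation and ligand genes shifted, but antigen processing genes did with no low-count filter (adjusted p = 0.0275, range 0.0275 to 0.628).

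Of 23 cholesterol biosynthesis genes, 16 fell and 7 did not pass (median -0.64, adjusted p = 2.08e-07). EBP, a sterol isomerase gene, went from 203 ± 6.57 to 63.5 ± 6.11 CPM (log2 fold change -1.68 ± 0.15, adjusted p = 9.25e-08) and the receptor gene LDLR from 205 ± 43.1 to 50.6 ± 7.61 CPM. Of 45 lysosome genes, 33 rose and 12 did not pass (35 rose adjusted over the list alone, median 0.84, adjusted p = 9.76e-12). PSAP, coding for the precursor of the saposins, went from 1042 ± 47.4 to 2041 ± 25.3 CPM (0.97 ± 0.11, adjusted p = 1.83e-06). Of 40 MYC target and ribosome biogenesis genes, 12 fell and 28 did not pass (median -0.33, adjusted p = 0.00543, but adjusted p = 0.240 with an estimated correlation, range 2.39e-05 to 0.240), FBL of the nucleolus among them (-1.02 ± 0.12, adjusted p = 2.35e-06). Of 26 unfolded protein response genes, 11 rose, 2 fell and 13 did not pass (13 rose and 2 fell adjusted over the list alone, median 0.37, adjusted p = 0.0193, but adjusted p = 0.206 with an estimated correlation, range 0.00206 to 0.206). The chaperone gene DNAJB9 rose (1.32 ± 0.15, adjusted p = 1.48e-06) and TRIB3 falling (-1.15 ± 0.13, adjusted p = 2.52e-06). Of 29 estrogen receptor target genes, 11 rose, 4 fell and 14 did not pass (13 rose and 4 fell adjusted over the list alone, median 0.44, adjusted p = 0.00189, but adjusted p = 0.182 with an estimated correlation, range 0.000111 to 0.182). The trefoil genes TFF1 (40.2 ± 10.9 to 319 ± 89.3 CPM, 2.98 ± 0.42, adjusted p = 2.18e-05) and TFF3 (1.88 ± 0.16, adjusted p = 4.89e-08) rose. ESR1 itself (-0.25 ± 0.11, adjusted p = 0.105) and ERBB2 (0.22 ± 0.33, adjusted p = 0.657) did not pass.

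The other lists did not shift in MDA-MB-361. Ribosomal protein genes did with no low-count filter (adjusted p = 0.0476). With fry 9 lists that did not shift passed, antigen processing, interferon receptor and checkpoint genes among them. Of 52 ribosomal protein genes, 1 rose and 5 fell (1 rose and 3 fell adjusted over the list alone, median -0.17, adjusted p = 0.291). Of 50 oxidative phosphorylation genes, 1 rose and 2 fell (1 rose and 1 fell adjusted over the list alone, median -0.15, adjusted p = 0.567). Of 24 luminal epithelial genes, 5 rose and 1 fell (median 0.23, adjusted p = 0.240). Of 19 basal, myoepithelial and squamous epithelial genes, 4 rose and 7 fell (median -0.18, adjusted p = 0.704). Of 15 mesenchymal genes, 2 rose and 5 fell (3 rose and 5 fell adjusted over the list alone, median 0.25, bounded 0.21, adjusted p = 0.240). Of 29 ERBB family and MAPK feedback genes, 6 rose and 8 fell (median 0.01, bounded -0.07, adjusted p = 0.882). AR rose (log2 fold change 0.81 ± 0.19, adjusted p = 0.00321) and KRT17 fell (-3.76 ± 0.38, adjusted p = 4.46e-07). Of 21 senescence-associated secretory genes, 8 rose and 7 fell (median -0.02, bounded -0.55, adjusted p = 0.704). Of 29 p53 target genes, 5 rose and 7 fell (7 rose and 10 fell adjusted over the list alone, median -0.14, adjusted p = 0.624). Of 17 heat shock genes, 2 rose (1 rose adjusted over the list alone, median 0.04, adjusted p = 0.537). Of 20 immediate early genes, 7 rose and 1 fell (7 rose and 2 fell adjusted over the list alone, median 0.43, adjusted p = 0.342). Of 27 apoptosis regulators, 2 rose and 3 fell (median -0.01, adjusted p = 0.882). IGFBP5 rose (1711 ± 134 to 6451 ± 639 CPM) and GDF15 fell (15.2 ± 1.45 to 0.961 ± 0.633 CPM). Genes typical of other cell types moved little as lists. Of 5 fibroblast genes, 1 rose (median 0.21, adjusted p = 0.255). Of 6 endothelial genes, 1 fell (median -0.17, adjusted p = 0.624). LUM went from 3 to 119 counts (39.5-fold (95% counting interval 13.2 to 194)). The mean of mesenchymal genes (-0.18) had the opposite sign to their median, and for secretory and basal genes the direction of the test was opposite to both.

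In MDA-MB-453 the same comparison gave a loss of cell division RNAs and a broad rise of interferon-stimulated and antigen presentation genes. Cholesterol synthesis and ribosome biogenesis genes fell, and lysosome genes rose. In all, 4868 genes changed (2417 rose and 2451 fell), 1039 rising and 1116 falling at least 2-fold, and 3125 changed when the 6 libraries of the line were fitted alone. The formyl peptide receptor gene FPR3 went from 3 to 925 counts (363-fold (95% counting interval 124 to 1765)). Other large rises were those of the interferon-stimulated genes OAS2 (log2 fold change 6.94 ± 0.64, adjusted p = 9.33e-08), IFIT3 (6.71 ± 0.77, adjusted p = 1.42e-06) and IFI27 (6.68 ± 0.60, adjusted p = 5.58e-08) and of CYP4F8 (6.32 ± 0.56, adjusted p = 1.64e-06). The lowest fold changes were those of the cell cycle genes RRM2 (-9.70 ± 0.32), KIAA0101 (-7.37 ± 0.19), HMGB2 (-7.33 ± 0.44), CENPA (-7.25 ± 0.41) and MYBL2 (-7.15 ± 0.31), with adjusted p at most 2.13e-10.

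Of 56 DNA replication and E2F target genes, 55 fell and 1 did not pass (56 fell adjusted over the list alone, median -2.54, adjusted p = 1.09e-88). RRM2 went from 667 ± 147 to 0.804 ± 0.186 CPM and CDC45 from 138 ± 13.6 to 4.27 ± 0.396 CPM. Of 66 G2/M and mitosis genes, 65 fell and 1 did not pass (median -3.76, adjusted p = 1.43e-82). MKI67 went from 312 ± 142 to 2.39 ± 0.472 CPM (log2 fold change -7.04 ± 0.41, adjusted p = 1.35e-10) and NUSAP1, a spindle protein gene, from 187 ± 39.7 to 2.25 ± 0.341 CPM. Of 35 replication-dependent histone genes, 2 rose, 32 fell and 1 did not pass (2 rose and 33 fell adjusted over the list alone, median -3.76, adjusted p = 1.63e-74). HIST1H4C went from 1082 ± 107 to 39.0 ± 4.92 CPM. Of 22 CDK, cyclin, RB and CDK inhibitor genes, 5 rose, 8 fell and 9 did not pass (5 rose and 11 fell adjusted over the list alone, median -0.35, adjusted p = 0.000120). CCNE2 (-4.55 ± 0.24, adjusted p = 2.92e-11), E2F1 (-2.55 ± 0.16, adjusted p = 5.20e-10) and CCNE1 (-1.79 ± 0.22, adjusted p = 3.60e-06) fell. CCND1 (0.82 ± 0.16, adjusted p = 0.000435) and CDKN1A (0.79 ± 0.19, adjusted p = 0.00314) rose. CDKN1A did not pass with the 6 libraries fitted alone (adjusted p = 0.0514, range 0.000172 to 0.0514). CDK6, at low levels (1.33 ± 0.569 to 2.21 ± 0.403 CPM), rose (0.76 ± 0.25, adjusted p = 0.0225). Leaving out single libraries ended that call, the log2 fold change being 0.58 with adjusted p = 0.118 without MDA-MB-453 control replicate 1, 0.60 with adjusted p = 0.0977 without MDA-MB-453 control replicate 2 and 0.61 with adjusted p = 0.111 without MDA-MB-453 abemaciclib replicate 1, as did the line alone (adjusted p = 0.174). CDK4 (-0.35 ± 0.14, adjusted p = 0.0560, but 0.00943 with the replicate block, range 0.00665 to 0.244) and RB1 (-0.17 ± 0.14, adjusted p = 0.385) did not pass. In the DNA methylation machinery (17 genes), 1 rose, 7 fell and 9 did not pass (1 rose and 10 fell adjusted over the list alone, median -0.36, adjusted p = 2.33e-06). UHRF1 (-3.79 ± 0.16, adjusted p = 1.76e-12) and DNMT1 (-1.56 ± 0.18, adjusted p = 1.14e-06) fell.

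Of 58 interferon-stimulated genes, 53 rose and 5 did not pass (median 3.76, bounded 3.44, adjusted p = 1.10e-30). STAT1 rose from 175 ± 48.7 to 1294 ± 443 CPM (log2 fold change 2.89 ± 0.22, adjusted p = 6.24e-09) and IFIT2, which binds viral RNA, from 1.58 ± 0.996 to 90.0 ± 50.1 CPM. In replicate 1 STAT1 stood higher in the control (231 CPM against 147 and 146) and lower when treated (807 against 1673 and 1401). Of 17 double-stranded RNA and nucleic acid sensing genes, 10 rose, 3 fell and 4 did not pass (median 1.43, adjusted p = 0.000340). DDX58, the RIG-I gene, went from 59.8 ± 10.6 to 1133 ± 708 CPM, while MB21D1, the cGAS gene, fell (-2.69 ± 0.28, adjusted p = 4.01e-07). Of 21 antigen processing and MHC class I genes, 17 rose and 4 did not pass (19 rose adjusted over the list alone, median 1.55, adjusted p = 1.47e-08). B2M (1.86 ± 0.26, adjusted p = 1.35e-05), HLA-A (1.09 ± 0.25, adjusted p = 0.00182), HLA-B (3.37 ± 0.45, adjusted p = 9.93e-06), TAP1 (16.9 ± 3.64 to 86.5 ± 27.9 CPM, 2.35 ± 0.22, adjusted p = 1.29e-07) and NLRC5 (0.747 ± 0.530 to 16.2 ± 7.10 CPM, 4.32 ± 0.45, adjusted p = 4.33e-07) rose together. CD274 had 11 counts over the 3 control and 7 over the 3 treated libraries and was not tested. Of 7 interferon ligands and receptors, 2 rose and 1 fell (median 0.21, adjusted p = 0.620). Of 13 immune checkpoint and costimulatory ligands, 2 rose and 4 fell (median -0.52, adjusted p = 0.858). Neither list shifted, and the mean of the latter (0.12) had the opposite sign to its median. PVRL2 rose (0.96 ± 0.20, adjusted p = 0.000940) and CD47 fell (-0.80 ± 0.20, adjusted p = 0.00466).

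Of 23 cholesterol biosynthesis genes, 1 rose, 18 fell and 4 did not pass (median -1.08, adjusted p = 4.26e-07). EBP went from 235 ± 4.76 to 58.0 ± 15.8 CPM (log2 fold change -2.02 ± 0.15, adjusted p = 6.24e-09). Of 45 lysosome genes, 26 rose and 19 did not pass (27 rose adjusted over the list alone, median 0.74, adjusted p = 2.36e-07). PSAP went from 682 ± 16.8 to 1725 ± 127 CPM (1.34 ± 0.11, adjusted p = 2.01e-08). Of 40 MYC target and ribosome biogenesis genes, 28 fell and 12 did not pass (30 fell adjusted over the list alone, median -0.62, adjusted p = 1.30e-07). FBL (-1.53 ± 0.12, adjusted p = 8.92e-09) and the polyamine enzyme gene ODC1 (-1.41 ± 0.13, adjusted p = 6.03e-08) fell. Of 52 ribosomal protein genes, 2 rose, 16 fell and 34 did not pass (2 rose and 15 fell adjusted over the list alone, median -0.30, adjusted p = 0.0282, but adjusted p = 0.3003 with an estimated correlation, range 0.000404 to 0.3003). That call also ended with a mean CPM of at least 10 (0.0737), in the line alone (0.0576) and without MDA-MB-453 control replicate 1 (median -0.27, adjusted p = 0.1001). Of 26 unfolded protein response genes, 8 rose, 3 fell and 15 did not pass (median 0.26, adjusted p = 0.0468, but adjusted p = 0.203 with an estimated correlation, range 0.0149 to 0.203). Single libraries ended that shift, the median being 0.29 with adjusted p = 0.0752 without MDA-MB-453 control replicate 1, 0.31 with adjusted p = 0.0860 without MDA-MB-453 control replicate 3 and 0.24 with adjusted p = 0.0671 without MDA-MB-453 abemaciclib replicate 3. DDIT4, a stress-induced inhibitor of mTORC1, rose (2.83 ± 0.21, adjusted p = 3.43e-09). Of 21 senescence-associated secretory genes, 6 rose, 1 fell and 14 did not pass (5 rose and 1 fell adjusted over the list alone, median 0.82, bounded 0.43, adjusted p = 0.0254, but adjusted p = 0.178 with a mean CPM of at least 10, range 0.00255 to 0.178). The chemokine gene CCL5 went from 0.220 ± 0.178 to 16.9 ± 6.75 CPM (6.27 ± 0.44, adjusted p = 2.27e-09). Of 24 luminal epithelial genes, 9 rose, 1 fell and 14 did not pass (median 0.46, adjusted p = 0.0142, but adjusted p = 0.184 with an estimated correlation, range 0.000587 to 0.184). The secretory protein gene PIP (5.42 ± 0.53, adjusted p = 4.72e-07) and AR (169 ± 26.0 to 436 ± 138 CPM, 1.36 ± 0.19, adjusted p = 1.61e-05) rose. Of 20 immediate early genes, 8 rose and 12 did not pass (10 rose adjusted over the list alone, median 0.77, bounded 0.88, adjusted p = 0.0153, but adjusted p = 0.285 with an estimated correlation, range 0.00193 to 0.285). JUNB rose (1.58 ± 0.21, adjusted p = 1.07e-05).

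ERBB2 rose in MDA-MB-453 (108 ± 67.7 to 226 ± 79.5 CPM, log2 fold change 1.06 ± 0.33, adjusted p = 0.0162). Leaving out single libraries ended that call, the log2 fold change being 0.82 with adjusted p = 0.0857 without MDA-MB-453 control replicate 2, 0.83 with adjusted p = 0.0842 without MDA-MB-453 control replicate 3 and 0.77 with adjusted p = 0.0862 without MDA-MB-453 abemaciclib replicate 1. It also ended in the line alone (adjusted p = 0.0915, range 4.47e-09 to 0.0915). ESR1 had no counts. The remaining lists did not shift in this line. Basal genes did in the line alone (adjusted p = 0.0257) and with the block in MDA-MB-361 and MDA-MB-453 only (0.0407), and 8 lists that did not shift passed with fry. Of 29 estrogen receptor target genes, 7 rose and 8 fell (8 rose and 9 fell adjusted over the list alone, median -0.28, bounded -0.34, adjusted p = 0.858). Of 19 basal, myoepithelial and squamous epithelial genes, 6 rose and 5 fell (median 1.59, bounded 1.25, adjusted p = 0.106). Of 15 mesenchymal genes, 1 rose and 1 fell (median -0.42, bounded -0.47, adjusted p = 0.743). Of 29 ERBB family and MAPK feedback genes, 12 rose and 6 fell (median 0.42, adjusted p = 0.211). Of 50 oxidative phosphorylation genes, 1 rose and 7 fell (1 rose and 5 fell adjusted over the list alone, median -0.20, adjusted p = 0.395). Of 29 p53 target genes, 8 rose and 6 fell (median 0.30, adjusted p = 0.128). Of 17 heat shock genes, 2 rose and 6 fell (2 rose and 8 fell adjusted over the list alone, median -0.36, bounded -0.37, adjusted p = 0.397). Of 27 apoptosis regulators, 6 rose and 6 fell (median 0.15, adjusted p = 0.414). Of 5 fibroblast genes, 1 fell (median -0.47, adjusted p = 0.713). Of 6 endothelial genes, 1 fell (median -1.86, bounded -1.33, adjusted p = 0.743). KRT17 went from 2 to 266 counts (157-fold (95% counting interval 43.0 to 1301)). IL17RB (-3.85 ± 0.31, adjusted p = 1.52e-08) and TNC (-1.35 ± 0.18, adjusted p = 2.20e-05) fell.

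In MCF7, at the lower dose, cell division genes fell and interferon-stimulated genes rose as a class, and secretory and basal genes rose with them. The lists of ribosomal protein and estrogen receptor target genes shifted down, the latter not with an estimated correlation. This line had the most changed genes, 6215 (3351 rose and 2864 fell), 1840 rising and 1391 falling at least 2-fold. The ubiquitin-like gene UBD went from 2 to 619 counts (280.3-fold (95% counting interval 77.3 to 2319.8)) and RSAD2, coding for the antiviral protein viperin, from 3 to 623 (188-fold (95% counting interval 64.1 to 915)). Large rises followed in SERPINA11 (7.39 ± 0.37), IFI27 (7.18 ± 0.58), SAMD9 (6.91 ± 0.51) and IFI44L (6.78 ± 0.81), with adjusted p at most 2.66e-06. The lowest fold changes included WDR76 (-6.29 ± 0.33), HIST1H3B (-6.05 ± 0.26) and HMGB2 (-5.70 ± 0.41), with adjusted p at most 1.35e-09.

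Among 56 DNA replication and E2F target genes, 55 fell and 1 did not pass (56 fell adjusted over the list alone, median -3.02, adjusted p = 2.46e-72). The thymidine kinase gene TK1 went from 436 ± 45.2 to 15.7 ± 0.315 CPM. Among 66 G2/M and mitosis genes, 66 fell (median -4.39, adjusted p = 3.40e-73). MKI67 went from 407 ± 57.8 to 16.1 ± 1.46 CPM (log2 fold change -4.65 ± 0.35, adjusted p = 2.97e-09) and the mitotic transcription factor gene FOXM1 from 79.7 ± 3.31 to 3.01 ± 0.0826 CPM. Among 35 replication-dependent histone genes, 1 rose, 31 fell and 3 did not pass (2 rose and 31 fell adjusted over the list alone, median -3.13, adjusted p = 3.46e-46). HIST1H4A went from 197 ± 12.6 to 3.53 ± 0.7996 CPM. Of 22 CDK, cyclin, RB and CDK inhibitor genes, 5 rose and 10 fell (5 rose and 11 fell adjusted over the list alone, median -0.23, bounded -0.46, adjusted p = 0.120). This list did not shift. The CDK inhibitor genes CDKN2B (42.3 ± 3.62 to 585 ± 33.8 CPM, 3.79 ± 0.17, adjusted p = 3.25e-12) and CDKN1A (1.81 ± 0.18, adjusted p = 1.13e-07) rose with CDK6 (1.09 ± 0.16, adjusted p = 1.19e-05) and CCND1 (0.80 ± 0.16, adjusted p = 0.000360). CCNE2 (-4.08 ± 0.26, adjusted p = 2.63e-10), E2F1 (-2.90 ± 0.17, adjusted p = 1.05e-10) and CDK4 (-0.79 ± 0.14, adjusted p = 0.000134) fell. CCNE1 did not pass (-0.01 ± 0.20, adjusted p = 0.989). RB1 fell (-0.46 ± 0.14, adjusted p = 0.0131). Single libraries ended that call, the log2 fold change being -0.36 with adjusted p = 0.0753 without MCF7 control replicate 1 and -0.40 with adjusted p = 0.0603 without MCF7 abemaciclib replicate 1. In the DNA methylation machinery (17 genes), 1 rose, 9 fell and 7 did not pass (median -0.40, adjusted p = 6.60e-05). UHRF1 (-4.16 ± 0.17, adjusted p = 1.15e-12) and DNMT1 (-1.88 ± 0.18, adjusted p = 6.60e-08) fell.

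Among 58 interferon-stimulated genes, 57 rose and 1 did not pass (median 3.77, adjusted p = 8.78e-32). BST2, coding for the virus-tethering protein tetherin, went from 48.1 ± 5.33 to 1148 ± 81.8 CPM (log2 fold change 4.58 ± 0.20, adjusted p = 3.25e-12) and STAT1 from 204 ± 17.9 to 1246 ± 76.0 CPM (2.61 ± 0.22, adjusted p = 1.19e-08). Among 17 double-stranded RNA and nucleic acid sensing genes, 12 rose, 2 fell and 3 did not pass (12 rose and 3 fell adjusted over the list alone, median 1.78, bounded 1.59, adjusted p = 0.000115). IFIH1, the MDA5 gene, went from 1.23 ± 0.322 to 24.6 ± 1.93 CPM and OAS1 from 4.33 ± 1.01 to 269 ± 2.54 CPM. Among 21 antigen processing and MHC class I genes, 17 rose, 1 fell and 3 did not pass (17 rose and 2 fell adjusted over the list alone, median 1.69, adjusted p = 9.91e-07, but adjusted p = 0.0531 with an estimated correlation, range 1.42e-07 to 0.0531). TAP1 (15.4 ± 0.528 to 146 ± 6.19 CPM, 3.24 ± 0.23, adjusted p = 1.37e-09), B2M (1.69 ± 0.26, adjusted p = 2.16e-05), NLRC5 (3.42 ± 0.54, adjusted p = 3.92e-05) and HLA-A (1.30 ± 0.32, adjusted p = 0.00279) rose. HLA-B had 1 count in controls and 5 in treated libraries (4.53-fold (95% counting interval 0.507 to 214)). CD274 had 6 counts over the 3 control and 15 over the 3 treated libraries. Among 13 immune checkpoint and costimulatory ligands, 7 rose and 6 did not pass (median 0.62, adjusted p = 0.0192, but adjusted p = 0.0740 with a mean CPM of at least 10, range 0.0136 to 0.0740). The stress ligand gene ULBP2 went from 6.51 ± 0.477 to 25.1 ± 0.712 CPM. Of 7 interferon ligands and receptors, 5 rose (median 0.60, adjusted p = 0.0706). This list shifted with the replicate block (adjusted p = 0.0451) and with no low-count filter (0.0174, range 0.0174 to 0.106). IFNGR1 rose (1.80 ± 0.17, adjusted p = 7.75e-08).

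Among 21 senescence-associated secretory genes, 15 rose, 1 fell and 5 did not pass (median 1.51, adjusted p = 5.21e-08). The growth factor gene TGFB2 went from 4.37 ± 0.541 to 113 ± 7.59 CPM (log2 fold change 4.70 ± 0.23, adjusted p = 1.33e-11) and TIMP2, a protease inhibitor gene, from 79.5 ± 1.27 to 699 ± 21.0 CPM. Among 19 basal, myoepithelial and squamous epithelial genes, 13 rose, 1 fell and 5 did not pass (14 rose and 1 fell adjusted over the list alone, median 1.78, adjusted p = 3.76e-06). The laminin gene LAMC2 went from 6.35 ± 1.10 to 88.9 ± 6.57 CPM. Among 27 apoptosis regulators, 16 rose and 11 did not pass (median 0.75, adjusted p = 0.00736). The survival gene BCL2L1 rose (1.17 ± 0.12, adjusted p = 1.83e-07). Among 45 lysosome genes, 39 rose, 1 fell and 5 did not pass (40 rose and 1 fell adjusted over the list alone, median 0.97, adjusted p = 4.30e-09). PSAP went from 753 ± 58.6 to 1937 ± 105 CPM (1.36 ± 0.11, adjusted p = 9.30e-09). Among 20 immediate early genes, 10 rose, 2 fell and 8 did not pass (10 rose and 3 fell adjusted over the list alone, median 0.87, adjusted p = 0.0192, but adjusted p = 0.253 with an estimated correlation, range 0.00370 to 0.253, and 0.170 with a mean CPM of at least 10). KLF6 rose (2.16 ± 0.18, adjusted p = 9.05e-09). Among 52 ribosomal protein genes, 42 fell and 10 did not pass (45 fell adjusted over the list alone, median -0.67, adjusted p = 3.80e-07). RPL5 went from 612 ± 45.2 to 303 ± 18.8 CPM (-1.01 ± 0.12, adjusted p = 1.23e-06) and RPS8 from 2986 ± 103 to 1419 ± 41.0 CPM. Among 40 MYC target and ribosome biogenesis genes, 26 fell and 14 did not pass (28 fell adjusted over the list alone, median -0.55, adjusted p = 6.84e-06). FBL fell (-1.94 ± 0.12, adjusted p = 2.14e-10). Among 50 oxidative phosphorylation genes, 23 fell and 27 did not pass (median -0.50, adjusted p = 0.00104, but adjusted p = 0.137 with an estimated correlation, range 9.55e-07 to 0.137). NDUFB8 of complex I fell (-1.11 ± 0.12, adjusted p = 2.50e-07). Among 23 cholesterol biosynthesis genes, 1 rose, 14 fell and 8 did not pass (median -0.58, adjusted p = 0.000318). EBP went from 169 ± 7.06 to 40.7 ± 3.30 CPM (-2.05 ± 0.15, adjusted p = 3.01e-09). Among 29 estrogen receptor target genes, 2 rose, 16 fell and 11 did not pass (median -0.52, adjusted p = 0.000191, but adjusted p = 0.0534 with an estimated correlation, range 5.41e-05 to 0.0534). ESR1 went from 202 ± 2.21 to 69.9 ± 3.60 CPM (-1.53 ± 0.12, adjusted p = 4.14e-08) and its target GREB1 from 196 ± 14.3 to 51.3 ± 5.13 CPM.

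ERBB2 rose in MCF7 (22.0 ± 2.17 to 42.6 ± 2.52 CPM, log2 fold change 0.95 ± 0.35, adjusted p = 0.0294). Single libraries ended that call, the log2 fold change being 1.03 with adjusted p = 0.0517 without MCF7 control replicate 1, 0.95 with adjusted p = 0.0696 without MCF7 control replicate 2, 0.88 with adjusted p = 0.0906 without MCF7 control replicate 3, 0.94 with adjusted p = 0.0621 without MCF7 abemaciclib replicate 1 and 0.92 with adjusted p = 0.0676 without MCF7 abemaciclib replicate 3. The remaining lists did not shift in MCF7. With fry, 9 lists that did not shift passed. Of 24 luminal epithelial genes, 11 rose and 4 fell (median 0.65, bounded 0.74, adjusted p = 0.294). Of 15 mesenchymal genes, 5 rose and 3 fell (median 0.31, adjusted p = 0.436). Of 29 ERBB family and MAPK feedback genes, 10 rose and 6 fell (10 rose and 7 fell adjusted over the list alone, median 0.20, bounded 0.10, adjusted p = 0.487). Of 29 p53 target genes, 11 rose and 8 fell (11 rose and 9 fell adjusted over the list alone, median 0.14, adjusted p = 0.487). Of 26 unfolded protein response genes, 11 rose and 6 fell (12 rose and 6 fell adjusted over the list alone, median 0.26, adjusted p = 0.487). Of 17 heat shock genes, 2 rose and 1 fell (1 rose and 0 fell adjusted over the list alone, median 0.10, bounded 0.09, adjusted p = 0.749). Of 5 fibroblast genes, 2 rose and 1 fell (median 0.92, adjusted p = 0.275). Of 6 endothelial genes, 3 rose (median 1.73, bounded 1.41, adjusted p = 0.162). LUM had no counts in controls and 84 in treated libraries, at least 25.4-fold higher.

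**Figure D2:**
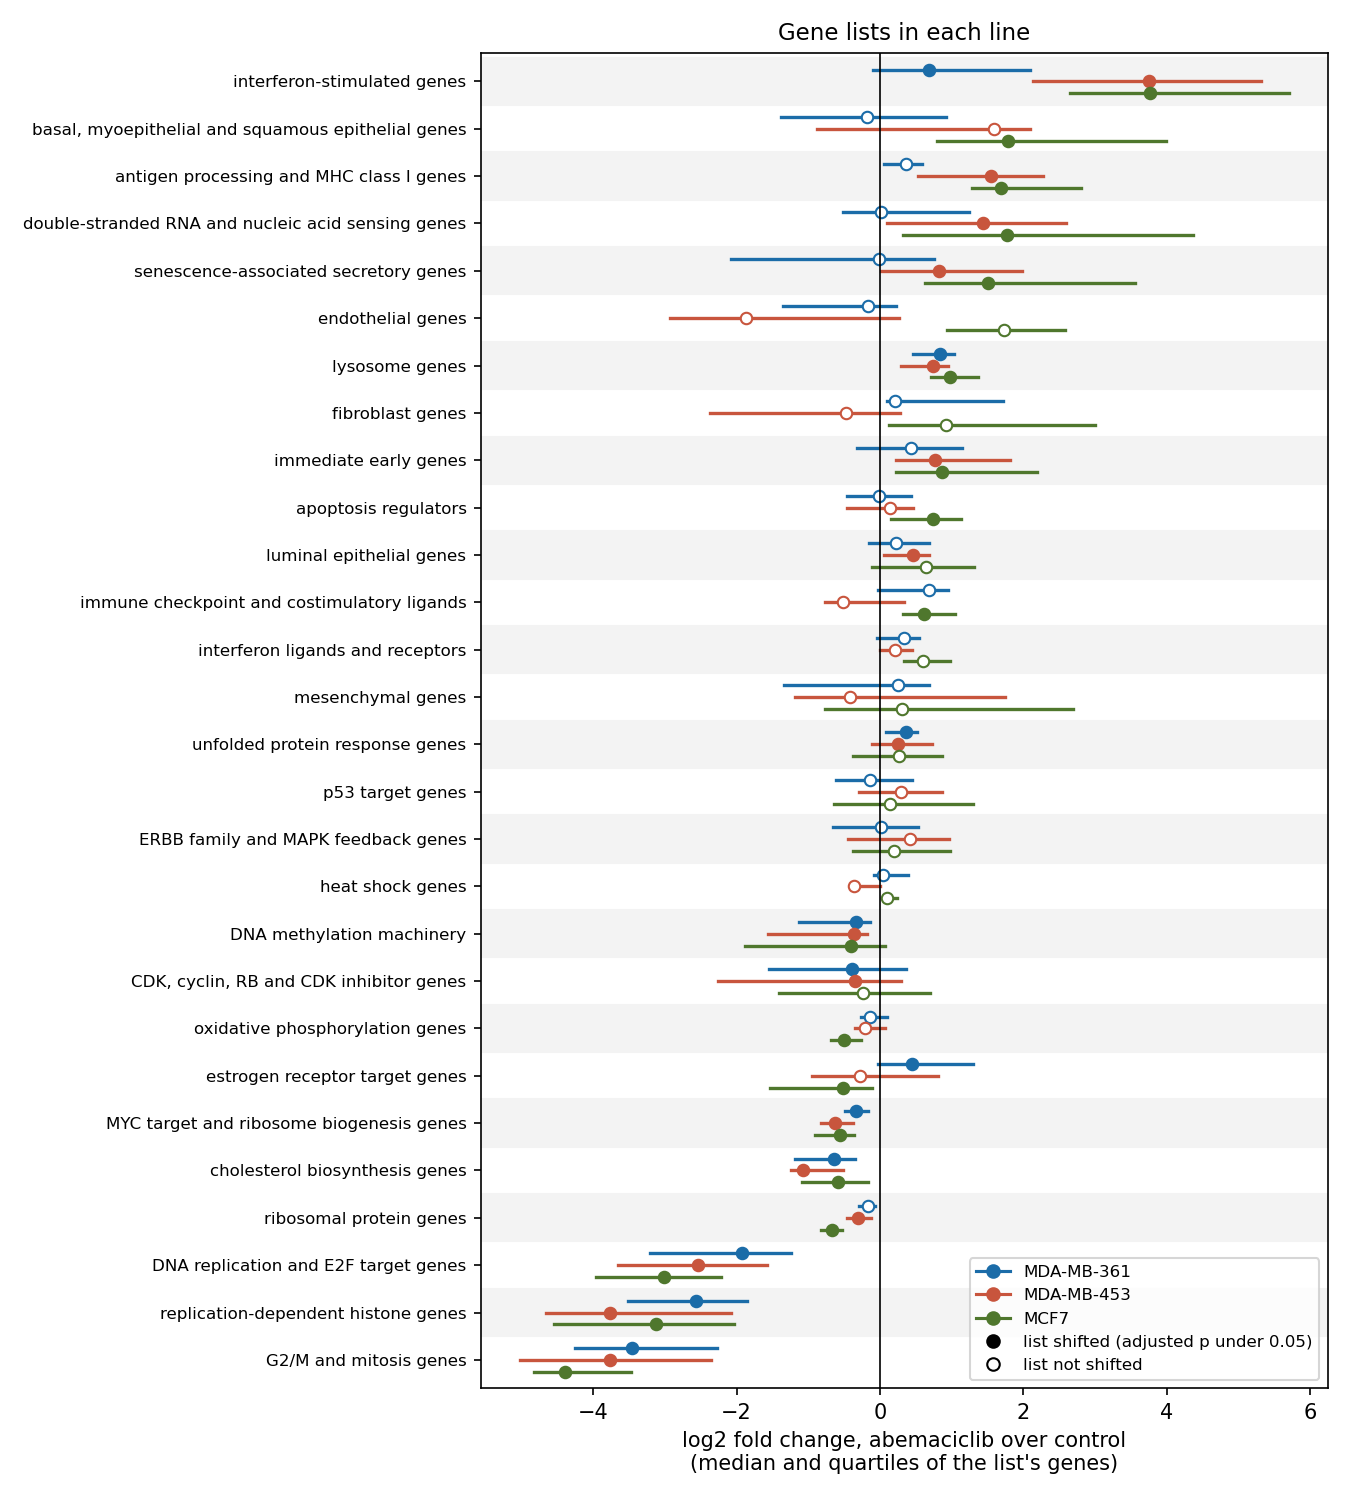
Median and quartiles of log2 fold change (treated over control) of each of 28 gene lists in each line, filled points marking lists that shifted. Mitosis genes lie lowest (medians -3.45, -3.76 and -4.39 in MDA-MB-361, MDA-MB-453 and MCF7), and interferon-stimulated genes lie at 0.69, 3.76 and 3.77.

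The average over the lines asks what they had in common. Lists that shifted alike in every line included lower cell cycle, DNA methylation and cholesterol synthesis RNAs and higher lysosome RNAs. On average 6897 genes changed (3589 rose, 3308 fell). The same 705 genes rose and the same 1016 fell in all 3 lines, 1721 in total, where independent lists would share 89.0 and 83.3, and the lines had their own controls. Across the 10145 genes with a mean CPM of at least 1 in each line, which are not independent replicates, log2 fold changes correlated at Pearson's r = 0.76 for MDA-MB-361 with MDA-MB-453, 0.68 for MDA-MB-361 with MCF7 and 0.72 for MDA-MB-453 with MCF7.

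Genes that rose in all 3 lines with the largest smallest change included IFI6 (log2 fold changes 2.49 ± 0.51, 5.46 ± 0.58 and 6.42 ± 0.61 in MDA-MB-361, MDA-MB-453 and MCF7), OAS1 (2.41 ± 0.49, 4.89 ± 0.51 and 5.96 ± 0.55) and the p53 target TP53INP1 (1.81 ± 0.21, 3.28 ± 0.23 and 2.40 ± 0.21). The phosphatase gene DUSP10 (1.94 ± 0.17, 1.79 ± 0.17 and 3.03 ± 0.19), IRF9 (1.77 ± 0.45, 2.40 ± 0.43 and 3.88 ± 0.46) and the extracellular chaperone gene CLU (1.70 ± 0.16, 1.74 ± 0.16 and 2.33 ± 0.16) followed. By the same measure the falls were led by HIST1H3F (-5.25 ± 0.22, -6.17 ± 0.23 and -5.72 ± 0.23), SPC25 (-5.08 ± 0.49, -6.92 ± 0.58 and -5.23 ± 0.51) and the PCNA-binding gene KIAA0101 (-5.05 ± 0.17, -7.37 ± 0.19 and -5.14 ± 0.17). For IFI6 in MDA-MB-453, control replicate 1 stood at 259.7 CPM and the other controls at 39.6 and 40.5. Without first replicates the log2 fold changes in MDA-MB-453 were 7.22 for IFI6 and 6.90 for OAS1.

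On average the lists that shifted up included antigen processing and MHC class I genes (median 1.25, adjusted p = 2.25e-07, but 0.0518 with an estimated correlation), interferon-stimulated genes (median 2.57, adjusted p = 7.67e-29) and double-stranded RNA and nucleic acid sensing genes (median 0.89, adjusted p = 6.87e-05). Also higher were senescence-associated secretory genes (median 0.81, adjusted p = 0.0268), lysosome genes (median 0.83, adjusted p = 4.99e-13) and immediate early genes (median 0.78, adjusted p = 0.0184, but 0.2999 with an estimated correlation). Those that shifted down included DNA replication and E2F target genes (median -2.40, adjusted p = 4.89e-109), G2/M and mitosis genes (median -3.73, adjusted p = 3.23e-114), CDK, cyclin, RB and CDK inhibitor genes (median -0.33, adjusted p = 0.000236) and DNA methylation machinery (median -0.31, adjusted p = 2.72e-07). Lower, too, were cholesterol biosynthesis genes (median -0.70, adjusted p = 1.52e-07), ribosomal protein genes (median -0.37, adjusted p = 0.000474, but 0.130 with an estimated correlation), MYC target and ribosome biogenesis genes (median -0.52, adjusted p = 5.28e-07) and replication-dependent histone genes (median -2.97, adjusted p = 5.80e-85). All others of these shifted with an estimated correlation as well, but secretory genes did not with a mean CPM of at least 10 (adjusted p = 0.0978). The other 14 lists did not shift on average, with adjusted p from 0.0524 (basal and unfolded protein response genes) to 0.971. Of these, oxidative phosphorylation, luminal and unfolded protein response genes did with the replicate block (adjusted p = 0.000606, 0.0160 and 0.0296), and 9 of the 14 passed with fry. For estrogen receptor targets and mesenchymal genes the median, the mean or the test differed in sign.

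**Figure D3:**
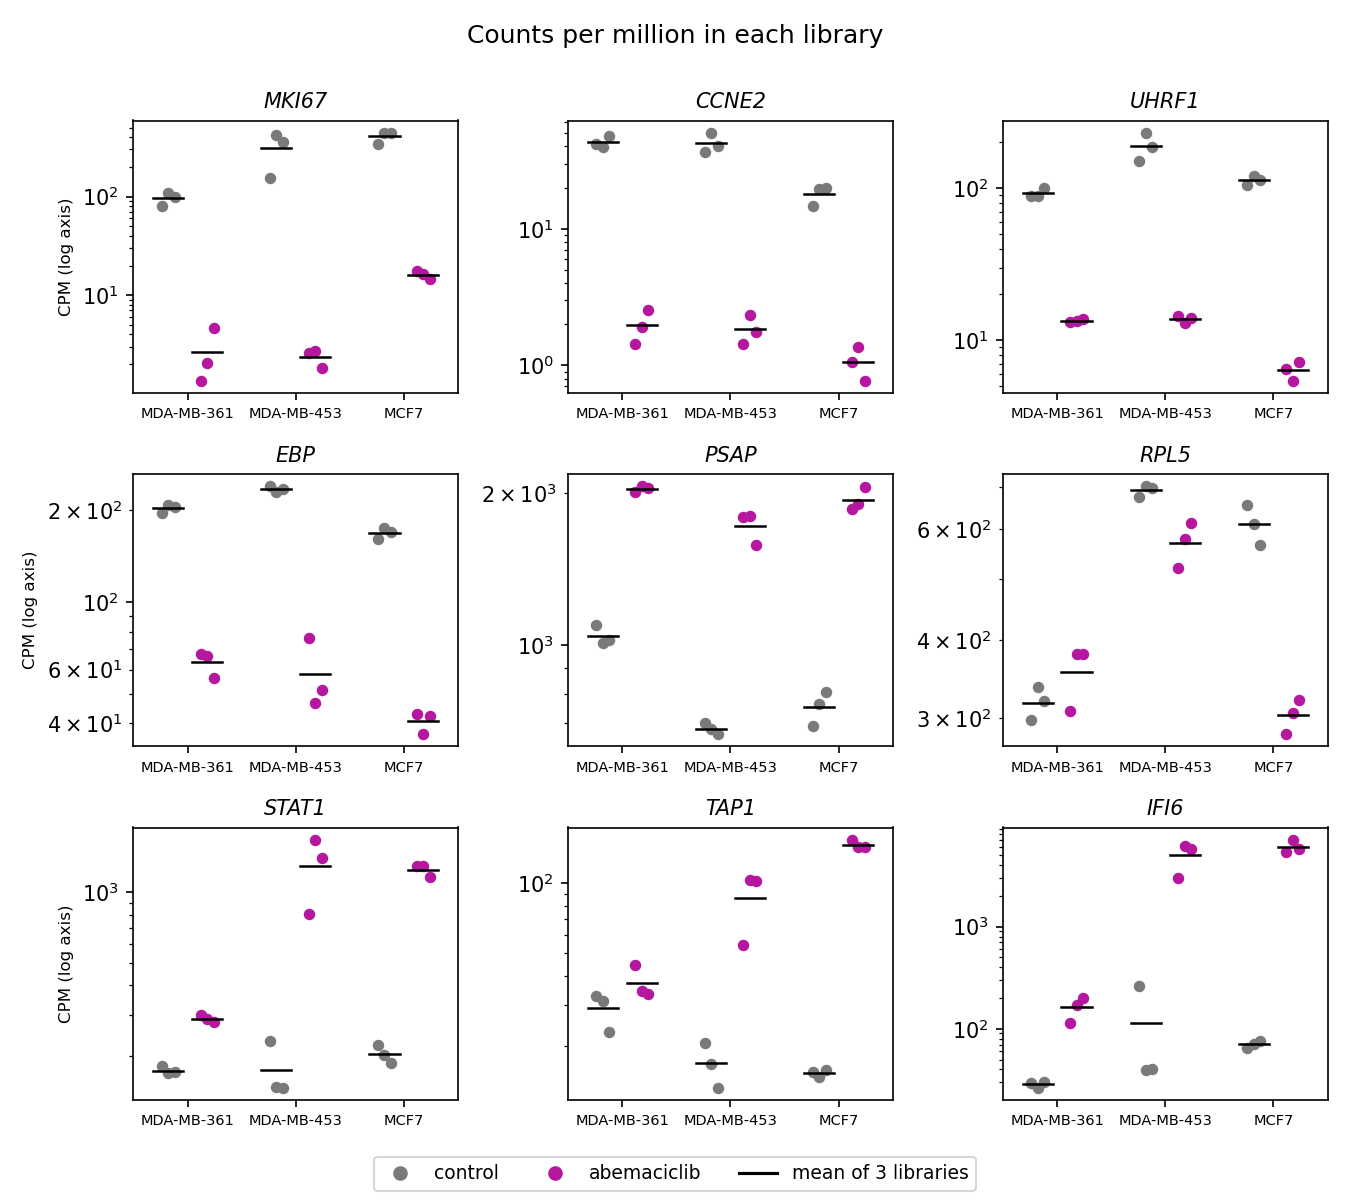
Level of 9 genes in every library, in CPM on a log axis, 1 point per library and a black line at the mean of 3, for control and treated cells of each line. MKI67, CCNE2, UHRF1 and EBP are lower and PSAP is higher in the treated cells of every line, while the treated mean of TAP1 is 37.5 CPM in MDA-MB-361, 86.5 in MDA-MB-453 and 146 in MCF7.

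Tests of the difference between lines ask where the response itself differed. Between MDA-MB-361 and MDA-MB-453, which had the same dose, replication RNAs fell less and interferon-stimulated RNAs rose less in MDA-MB-361. The responses of 1065 genes differed (530 higher and 535 lower in MDA-MB-361), and 2336 did with the replicate block. The estrogen-regulated gene TFF1 rose in MDA-MB-361 and fell in MDA-MB-453 (difference 5.23 ± 0.63, adjusted p = 3.66e-05). RRM2 fell by 5.25 on the log2 scale in MDA-MB-361 and by 9.70 in MDA-MB-453 (difference 4.45 ± 0.38, adjusted p = 9.71e-07). HIST1H2BB fell in MDA-MB-453 but not in MDA-MB-361 (difference 4.09 ± 0.53, adjusted p = 8.26e-05). The antiviral genes MX1 (difference -5.92 ± 0.74, adjusted p = 5.38e-05), CMPK2 (difference -5.29 ± 0.78, adjusted p = 0.000277) and HERC6 (difference -4.29 ± 0.71, adjusted p = 0.000738) rose in MDA-MB-453 but not in MDA-MB-361. YBX2 had no counts in treated MDA-MB-361, at least 15.04-fold lower, and fell less in MDA-MB-453 (log2 fold change -1.47 ± 0.19). Lists with a higher median response in MDA-MB-361 were DNA replication and E2F target genes (0.51, adjusted p = 1.25e-13), G2/M and mitosis genes (0.32, adjusted p = 0.00164), MYC target and ribosome biogenesis genes (0.32, adjusted p = 0.000137), estrogen receptor target genes (0.41, adjusted p = 3.02e-05) and replication-dependent histone genes (0.75, adjusted p = 6.12e-10). Those with a lower one were antigen processing and MHC class I genes (-0.94, adjusted p = 7.45e-09), interferon-stimulated genes (-2.65, adjusted p = 3.50e-40), double-stranded RNA and nucleic acid sensing genes (-1.19, adjusted p = 1.18e-08), p53 target genes (-0.28, adjusted p = 0.00304) and basal, myoepithelial and squamous epithelial genes (-1.31, adjusted p = 0.00304). All of these but mitosis, antigen processing, MYC target, estrogen receptor target and histone genes differed with an estimated correlation as well. Another 4 lists passed with all libraries but not without certain single ones, and the other 14 of 28 did not pass. With fry 5 more passed, and mitosis and immediate early genes did not (adjusted p = 0.249 and 0.0530).

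Between MDA-MB-361 and MCF7, whose doses differed, the response of interferon-stimulated, secretory and basal genes was higher in MCF7. Estrogen receptor targets shifted up in MDA-MB-361 and down in MCF7, in neither with an estimated correlation. The responses of 2684 genes differed (1168 higher and 1516 lower in MDA-MB-361), and 4278 did with the replicate block. The kinesin gene KIF5C (difference 4.85 ± 0.36, adjusted p = 3.08e-08) and SGCG (difference 4.34 ± 0.36, adjusted p = 9.39e-07) rose in MDA-MB-361 and had negative log2 fold changes in MCF7. METTL7A fell in MCF7 only (difference 4.41 ± 0.59, adjusted p = 3.15e-05). SOX3 had no counts in MDA-MB-361 controls and was at least 3.66-fold higher when treated, while it fell in MCF7 (log2 fold change -1.85 ± 0.17). TMPRSS4, a membrane protease gene (difference -7.11 ± 0.32, adjusted p = 1.17e-10), the cytokine gene GDF15 (difference -6.96 ± 0.75, adjusted p = 2.58e-06) and TGFB2 (difference -6.77 ± 0.45, adjusted p = 9.38e-09) fell in MDA-MB-361 and rose in MCF7. CEACAM1 went from 3 to 452 counts in MCF7 (136-fold (95% counting interval 46.4 to 664)) and did not pass in MDA-MB-361 (log2 fold change 0.29 ± 0.19). Lists with a higher median response in MDA-MB-361 were DNA replication and E2F target genes (0.97, adjusted p = 3.78e-14), G2/M and mitosis genes (0.81, adjusted p = 1.43e-07), oxidative phosphorylation genes (0.40, adjusted p = 0.000674) and ribosomal protein genes (0.46, adjusted p = 2.84e-07). The same held for MYC target and ribosome biogenesis genes (0.24, adjusted p = 0.00358), estrogen receptor target genes (0.96, adjusted p = 1.75e-15) and replication-dependent histone genes (0.47, adjusted p = 0.000419). Those with a lower one were antigen processing and MHC class I genes (-1.14, adjusted p = 8.96e-07), interferon-stimulated genes (-3.14, adjusted p = 1.56e-35), double-stranded RNA and nucleic acid sensing genes (-2.03, adjusted p = 6.01e-07) and senescence-associated secretory genes (-2.52, adjusted p = 1.04e-06). The same held for basal, myoepithelial and squamous epithelial genes (-2.59, adjusted p = 1.42e-06) and apoptosis regulators (-0.81, adjusted p = 0.000536). All of these but mitosis, antigen processing, oxidative phosphorylation, MYC target and histone genes differed with an estimated correlation as well. The other 15 of 28 lists did not pass. With fry 9 more passed.

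Between MDA-MB-453 and MCF7, again at different doses, few lists differed in a way that held in every leave-one-out fit. The responses of 2121 genes differed (926 higher and 1195 lower in MDA-MB-453), and 3490 did with the replicate block. The progestin receptor gene PAQR5 rose in MDA-MB-453 and fell in MCF7 (difference 5.74 ± 0.61, adjusted p = 2.62e-06). METTL7A fell in MCF7 only (difference 4.52 ± 0.60, adjusted p = 3.43e-05). SP140L had no counts in MDA-MB-453 controls and was at least 3.14-fold higher when treated, and did not pass in MCF7 (log2 fold change 0.03 ± 0.15). The matrix gene TNC fell in MDA-MB-453 (log2 fold change -1.35 ± 0.18) and was at least 7.25-fold higher in treated MCF7, whose controls had no counts. PIM1, a kinase gene, went from 138 to 2 counts in MDA-MB-453 and did not pass in MCF7 (log2 fold change 0.33 ± 0.20). SGCB was at least 5.66-fold lower in treated MDA-MB-453, without counts there. The mucin gene MUC20 rose in MCF7 (34.5 ± 2.74 to 869 ± 109 CPM). Lists with a higher median response in MDA-MB-453 were oxidative phosphorylation genes (0.28, adjusted p = 0.0106) and ribosomal protein genes (0.39, adjusted p = 0.000257). Neither difference held with an estimated correlation (adjusted p = 0.324 and 0.210). Another 7 lists passed with all libraries but not without certain single ones, and the other 19 of 28 did not pass. With fry 9 more passed, and mitosis and interferon-stimulated genes did not (adjusted p = 0.207 and 0.170).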

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

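The tests of a weaker cell cycle response and of first replicates alone below, and the fits with a block in MDA-MB-361 and MDA-MB-453 only or with first replicates left out, were chosen after the results were seen. The other tests in this part were set out beforehand.

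Responses that differed in a test of the difference itself came first. They numbered 1065 genes between MDA-MB-361 and MDA-MB-453, 2684 between MDA-MB-361 and MCF7 and 2121 between MDA-MB-453 and MCF7. Treatment was relabelled within lines in 59 random draws ignoring replicate number. Splits with a count at least as large include the real one. They were 1 of 60 for the first comparison (highest other 614), 2 of 60 for the second (3498) and 4 for the third (5803). Most draws take away the treatment effect, and the larger ones, 1 and 3 of 59, swapped every MCF7 label, turning a difference of responses into a sum. These splits decide nothing about chance in a difference. The average (6897 genes, highest other 988) was reached by 1 of 60, the lowest possible. So were genes changed the same way in all lines (1721, highest other 0 in edgeR, 2245 and 4 at an unadjusted p under 0.05). Both argue against chance. Within a line, 10 splits are too few for a share under 0.05, and 1 of 10 reached each real count. The real counts were 3867, 4868 and 6215 in MDA-MB-361, MDA-MB-453 and MCF7, and the highest others 0, 227 and 0 in edgeR (at an unadjusted p under 0.05, 5221, 5867 and 6992 against 1479, 3187 and 218).

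Of 28 lists, 19 differed between at least 1 pair of lines. Each is given with the median difference in the pair where its adjusted p was lowest (3.50e-40 to 0.0457 over the lists). For MDA-MB-361 minus MDA-MB-453 these were antigen processing and MHC class I genes (-0.94), interferon-stimulated genes (-2.65), double-stranded RNA and nucleic acid sensing genes (-1.19), p53 target genes (-0.28), MYC target and ribosome biogenesis genes (0.32) and replication-dependent histone genes (0.75). For MDA-MB-361 minus MCF7 they were DNA replication and E2F target genes (0.97), G2/M and mitosis genes (0.81), senescence-associated secretory genes (-2.52), oxidative phosphorylation genes (0.40), ribosomal protein genes (0.46), estrogen receptor target genes (0.96), basal, myoepithelial and squamous epithelial genes (-2.59) and apoptosis regulators (-0.81). With an estimated correlation the antigen processing, MYC target, histone, mitosis and oxidative phosphorylation lists, and the 5 lists below, no longer passed (adjusted p 0.0553 to 0.344). These 5 did not pass without the single libraries named next, with medians and, in brackets, adjusted p. Immune checkpoint and costimulatory ligands (-0.65, MDA-MB-453 minus MCF7) went to -0.90 (0.107) without MDA-MB-453 control replicate 1. Lysosome genes (-0.42, MDA-MB-453 minus MCF7) went to -0.35 (0.107) without MDA-MB-453 control replicate 1. Luminal epithelial genes (-0.28, MDA-MB-361 minus MDA-MB-453) went to -0.18 (0.0926) without MDA-MB-361 control replicate 1, and -0.26 (0.0561) and -0.19 (0.0546) without MDA-MB-453 control replicates 2 and 3. Heat shock genes (0.33, MDA-MB-361 minus MDA-MB-453) went to 0.36 (0.0988) and 0.33 (0.0683) without MDA-MB-361 control replicates 1 and 3, 0.32 (0.0805) without MDA-MB-361 abemaciclib replicate 2, 0.25 (0.103) and 0.41 (0.0586) without MDA-MB-453 control replicates 2 and 3, and 0.24 (0.0816) without MDA-MB-453 abemaciclib replicate 1. Immediate early genes (-0.67, MDA-MB-361 minus MDA-MB-453) went to -0.44 (0.119) without MDA-MB-453 abemaciclib replicate 3.

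Of 79 genes set apart by size of change or always eligible, 56 differed between lines in a test over all 3 (adjusted p 5.87e-10 to 0.0465), and 23 did not. Some were picked for differing, so this is no rate. The largest difference in log2 fold change among pairs that passed is given, without lines where both groups had 3 counts or fewer. MDA-MB-361 minus MDA-MB-453 was largest for BHLHE40 (3.48), CMPK2 (-5.29), HERC6 (-4.29), HIST1H1B (1.93), HIST1H2BB (4.09), HMGB2 (2.66), KIAA0101 (2.32), MX1 (-5.92), NLRC5 (-4.78), STAT1 (-2.15), TFF1 (5.23), TP53INP1 (-1.47) and WDR76 (2.08). MDA-MB-361 minus MCF7 was largest for CDKN1A (-2.24), E2F1 (1.29), ESR1 (1.27), GDF15 (-6.96), HIST1H3B (2.16), HIST1H4A (1.54), IFI6 (-3.93), KIF5C (4.85), OAS1 (-3.55), PKIA (2.54), SAMD9 (-4.81), SERPINA11 (-3.79), SGCG (4.34), TAP1 (-2.88), TGFB2 (-6.77), TMPRSS4 (-7.11), TTR (4.09), UHRF1 (1.36) and VSTM2A (5.58). MDA-MB-453 minus MCF7 was largest for CCNE1 (-1.78), CENPA (-2.96), DUSP10 (-1.24), IQGAP3 (-1.99), METTL7A (4.52), MKI67 (-2.38), MYBL2 (-2.58), PAQR5 (5.74), RRM2 (-5.06) and UGT2B15 (5.73).

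For 11 of these genes a group of 3 libraries had 3 counts or fewer, so the fitted difference depends on the prior count and is no bound. They were CEACAM1 (-6.64, MDA-MB-361 minus MCF7), MUC20 (-5.93, MDA-MB-453 minus MCF7), PIM1 (-6.07, MDA-MB-453 minus MCF7), SGCB (-6.06, MDA-MB-453 minus MCF7), SOX3 (6.56, MDA-MB-361 minus MCF7), SP140L (4.59, MDA-MB-453 minus MCF7), TNC (-7.45, MDA-MB-453 minus MCF7), UBD (-9.45, MDA-MB-361 minus MCF7) and YBX2 (-5.25, MDA-MB-361 minus MDA-MB-453). The remaining 2 and 3 genes with more counts did not pass in their pair without single libraries (differences with adjusted p in brackets). AKT3 (-5.27, MDA-MB-453 minus MCF7) gave -3.85 (0.151) without MDA-MB-453 control replicate 2 and -5.28 (0.0505) without MDA-MB-453 abemaciclib replicate 3. B2M (-1.30, MDA-MB-361 minus MDA-MB-453) gave -1.14 (0.0719) without MDA-MB-361 control replicate 2, -1.14 (0.0717) without MDA-MB-361 abemaciclib replicate 1, -1.31 (0.0554) without MDA-MB-453 control replicate 2, and -1.01 (0.0741) and -1.20 (0.0718) without MDA-MB-453 abemaciclib replicates 2 and 3. IRF9 (-2.11, MDA-MB-361 minus MCF7) gave -2.05 (0.0504) and -2.00 (0.0548) without MCF7 control replicates 1 and 3. PLK1 (-1.23, MDA-MB-453 minus MCF7) gave -1.05 (0.0607) without MDA-MB-453 control replicate 3, -1.15 (0.0564) and -1.12 (0.0792) without MDA-MB-453 abemaciclib replicates 1 and 3, -1.18 (0.0545) and -1.20 (0.0532) without MCF7 control replicates 1 and 2, and -1.22 (0.0526) and -1.22 (0.0505) without MCF7 abemaciclib replicates 1 and 2. RSAD2 (-4.21, MDA-MB-361 minus MCF7) gave -3.88 (0.124) and -4.25 (0.0619) without MDA-MB-361 control replicates 1 and 3, -4.00 (0.0510) without MDA-MB-361 abemaciclib replicate 1, -3.63 (0.0874) and -3.75 (0.0784) without MCF7 control replicates 1 and 2, and -4.12 (0.0504) and -4.14 (0.0502) without MCF7 abemaciclib replicates 2 and 3.

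The 4 first-replicate libraries of MDA-MB-361 and MDA-MB-453 deviated from their group means together. Depth was argued against, since their mean correlation was 0.466 after thinning all libraries to 7913151 counts (0.488 before). GC content stays open and cannot be told apart from other causes: the mean deviation correlated with transcript GC at a Spearman's rho of 0.286 across genes (0.162 to 0.306 per library, -0.124 to 0.116 in MCF7), and at 0.340 among genes with a mean CPM of at least 10. A different growth state could not be decided either, the cell cycle lists deviating by -0.30 at most (medians -0.08, -0.30, -0.29 and -0.02). A shared day or batch may underlie it, but the labels give none.

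Interferon-stimulated genes rose less in MDA-MB-361. A start near a ceiling was argued against, its controls lying below treated MDA-MB-453 for 47 of 58 genes (median log2 -2.55, pseudocount 0.5 CPM). So were first replicates alone holding the rise down (median 0.66 without them, 0.65 with the block, which hardly moves a balanced fold). A slightly higher start (median log2 0.16 and 0.14 over MDA-MB-453 and MCF7 controls) and a weaker cell cycle response stay open. Median falls were 0.918 of those in MDA-MB-453 for mitosis, 0.757 for replication and 0.684 for histone genes. A property of the line is untested, and against MCF7 the dose is confounded.

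Ribosomal protein genes fell in MCF7 (median -0.67). In 10000 random lists matched on expression level the middle median was 0.00982 and the lowest -0.54, and on transcript length -0.10 and -0.65. The former argue against a trend with level. Length decides little with 1 short product per gene. Scaling stays open: library size alone (median -0.65) moved all genes by only 0.02, and no spike-ins give amounts.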

How the results depend on the processing

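The block in MDA-MB-361 and MDA-MB-453 only and fits without first replicates were chosen after seeing results.

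Counts moved by over 1.5 times as follows. With the replicate block in all lines, genes whose response differed rose from 1065 to 2336 between MDA-MB-361 and MDA-MB-453, from 2684 to 4278 between MDA-MB-361 and MCF7 and from 2121 to 3490 between MDA-MB-453 and MCF7. With the block in MDA-MB-361 and MDA-MB-453 only they rose to 2569, 4516 and 3715, the changed genes of MDA-MB-361 from 3867 to 5917 and those changed the same way in all lines from 1721 to 2623. Without first replicates, genes differing between MDA-MB-361 and MDA-MB-453 were 1857 and between MDA-MB-453 and MCF7 3300. Fitted alone, MDA-MB-453 had 3125 changed genes against 4868. Shifted lists in MDA-MB-361 went from 11 to 7 with an estimated correlation and to 19 with fry. The cause was not tested for these, except that a line alone leaves fewer libraries for the spread and fry sets a list against no change rather than against other genes.

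Directions turned in 5 results. The difference MDA-MB-361 minus MDA-MB-453 of senescence-associated secretory genes was -1.12, adjusted p = 0.0364, and 0.41, adjusted p = 0.699 with a mean CPM of at least 10, which left 11 of its genes. Without first replicates MDA-MB-453 minus MCF7 went from -0.67, adjusted p = 0.0233 to 0.29, adjusted p = 0.833 for interferon-stimulated genes, and from -0.50, adjusted p = 0.819 to 2.14, adjusted p = 0.0480 for IFI27, -0.96, adjusted p = 0.3995 to 0.83, adjusted p = 0.00132 for IFI6 and -1.07, adjusted p = 0.333 to 0.97, adjusted p = 0.00994 for OAS1. The cause was not tested.

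No other called direction turned, and signs turned without a call 329 times over all alternatives. Results for genes and lists that came to pass and that no longer passed were 6 and 6 of 1262 with RLE factors, 5 and 9 of 1262 with library size alone, 23 and 15 of 1262 with no low-count filter, 7 and 11 of 1015 with a mean CPM of at least 10, 30 and 6 of 1066 with DESeq2, 29 and 33 of 838 with each line alone, 0 and 38 of 196 with an estimated correlation, 58 and 5 of 196 with fry, 97 and 3 of 1262 with the replicate block, 107 and 1 of 1262 with the block in MDA-MB-361 and MDA-MB-453 only and 98 and 15 of 1262 with first replicates left out. With single libraries left out in turn, which leaves 2 in an arm, 120 and 410 of 9834 did, and no count of calls moved by over 1.5 times. Simulated 1.5-fold changes were recovered in 12 or 13 of 50 genes, with fewer genes changed than in the data. Depth, spread and number of libraries were not varied. Low depth leaves genes with 3 counts or fewer in a group with a bound or an interval only. The planned limma fit was not run.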

Other observations

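The genes named in this part, and the test of interferon lambda, were chosen after the results were seen. Some belong to lists with too few genes for a test. HLA-DRB1, of MHC class II, went from 12.8 ± 1.70 to 49.4 ± 6.12 CPM (log2 fold change 1.95, adjusted p = 7.24e-07) in MCF7. LCP1, typical of leukocytes, went from 5.07 ± 1.55 to 27.1 ± 3.78 CPM (log2 fold change 2.41, adjusted p = 1.95e-06) in MDA-MB-361, where CORO1A fell (log2 fold change -1.04, adjusted p = 0.000513).

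The 3 interferon lambda genes (the near-identical IL28A and IL28B, and the related IL29) were too low for the main tests. Their counts, summed over 3 controls and 3 treated libraries, were 1 and 7 in MDA-MB-361, 7 and 96 in MDA-MB-453 and 0 and 36 in MCF7. IFNB1 had 1 and 9 over all 9 controls and 9 treated libraries. Set against chance over the 18 libraries, 8000 relabellings of treatment within lines gave the lambda CPM a two-sided exact p of 0.0005. The genes were picked for their rise, so this is a description and no test.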
